A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

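Gene expression was measured in fission yeast, Schizosaccharomyces pombe, on 2 spotted cDNA arrays. Each array compared, in its 2 colours, a wild-type strain carrying a plasmid that expresses Ssn6 with a wild-type strain carrying the empty plasmid. Ssn6 is a subunit of the Ssn6-Tup11/12 transcriptional corepressor. Both cultures grew in minimal medium without uracil, which selects for the plasmid, at 30 °C, per the labels. Per the labels, the Ssn6 culture carried Cy3 on array 1 and Cy5 on array 2. The series' design text speaks of 2 RNA preparations and does not say which array each went to. The p-values therefore measure the spread between 2 arrays, which may be technical.

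Per the file headers, the deposited scanner files hold the brightness of each spot in channel A and channel B, as an intensity already corrected for background. They also hold, per the file headers, the background intensity, the linear ratio of the channels by mean and by median, a saturation factor given as a fraction from 0 to 1, the spot's pixel area and a letter flag per channel. The headers name the channels A and B without a dye or a culture. The scanner software, the array grid and the gene annotation are not given in the sources used here. The formula of the saturation factor and the meaning of the flags are also not given in them. Spots without a signal have the value 0 in both channels.

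The authors' deposited value table holds lowess-normalized values per array, per the series' design text, on a log10 scale. Its scale, centring and direction were found by setting each column against that array's scanner values. The rows of its first part followed log10 of channel B over channel A, with r = 0.913 on array 1 and r = 0.939 on array 2 across spots, and slopes of 0.84 and 0.883. The remaining rows, from row 5761 of 11520 on, did not follow the spot order of the scanner files (r = 0.0355 and 0.0566) and were not used. The authors' values therefore rest on 1 spot per array for most genes. Each column had a median of 0.01. A value of -2.00 was a floor, held by 261 spots on array 1 and 145 on array 2, and was treated as missing. The labels do not say which culture each channel held in this table either; ssn6 had a log2 ratio of 2.29 in it.

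Each array had 11520 spots in 48 blocks, most probes being spotted 2 times. Of these, 10016 spots carried gene probes, and 9803 (97.9%) and 9995 (99.8%) of them had signal in both channels on arrays 1 and 2. Control spots, reporter genes, intergenic and intronic probes and probes the files name as missing were left out of the tests. The median gene signal was 75106 in channel A and 80936 in channel B on array 1, and 76752 and 90015.5 on array 2. The array number limits the precision: the test has 1 residual degree of freedom per gene, supplemented by 7.82 prior degrees of freedom that limma estimated across genes. An exact sign-flip test of 2 arrays cannot go below p = 0.5 for a single gene.

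The written design called for normexp background correction. The deposited columns were already corrected, so an offset of 50 was added to them instead, and normexp on the rebuilt signal became an added alternative. The log2 ratio of channel B over channel A was normalized within each array by loess with a span of 0.3, controls having weight 0. Spots of a probe were averaged. A gene was left out where its mean signal lay below the 95th percentile of the negative control spots in both channels of either array. This removed or left unmeasured 165 of 5006 gene probe names, and 4841 were tested. Of the probe names, 4777 were matched to the ASM294v3 gene table (3466 by locus tag, 945 by symbol, 366 by synonym), and 229 kept the files' names. A total of 24 genes were spotted under 2 names and appear with the file's name in brackets. Positions in that table were used only for which genes neighbour each other.

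The labels give each culture's dye, but neither they nor the file headers say which dye channel B holds. The sign of no array was turned. The overexpressed gene ssn6 was brighter in channel B on both arrays (log2 1.91 and 2.18), so that channel is likely the Ssn6 culture. The labelled dye swap would need opposite signs on the arrays if channel A were one dye throughout, and the arrays' ratios ran the same way across genes (r = 0.808). Ratios are therefore given as channel B over channel A, and dye bias may not cancel in their mean. The result with the sign of array 1 turned is given in the closing section. Saturated spots were kept, and genes that rest on them are named as such.

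Each gene's mean ratio was tested against 0 with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3, with tables read by the data.table package, 1.17.8), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes changed at least 1.5-fold in the same direction on both arrays were counted beside those changed in opposite directions. A list of 28 gene groups was written before the data were examined, and the 26 groups with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01. For a gene not above background in one channel of both arrays, a lower bound of the fold was computed from per-channel values after loess and Aquantile scaling. That bound is a mean over the arrays and is open to dye bias. Its floor was the lowest scaled value among genes above the limit of the negative controls, so a stricter floor would lower it. Plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

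The genes named were chosen by a rule written before the data were examined. It takes ssn6, tup11, tup12, ura4 and fbp1. It adds the 12 highest and 12 lowest genes past the threshold, ranked by the smaller of the absolute log2 ratios of the arrays. It also adds up to 4 members of each gene list that passed camera or had at least 3 members changed 1.5-fold one way on both arrays. Other genes named below were chosen after their values were seen, unless they belong to a list that is described. No probe was matched to tup12.

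The tests were tested on simulated data built from the real spots' intensities, intensity trend and noise, with 200 changed genes among 4820 tested. Of the genes changed 1.5-fold, 28.4% were found. Of those changed 2-fold, 86.6% were found, and of those changed 4-fold, 100%. Of 150 calls, 7 were false. A list of 37 genes shifted 1.5-fold had an adjusted camera p of 1.44e-34, and 0 of the other 25 lists were called. The simulated noise was drawn separately for each gene and array, without bias common to both arrays or correlation between genes. False calls from those sources are therefore not covered. The simulated arrays correlated with r = 0.416, against 0.808 in the data.

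The alternatives were no background correction, plain subtraction, print-tip loess, median centring, no filter on dim probes, the spot median ratio, the authors' deposited values, an intensity trend in the prior, each array left out, a 2-fold threshold and an estimated inter-gene correlation. Alternatives chosen after seeing the data were normexp on the rebuilt signal, spots with flag C only, no saturated spots, the sign of array 1 turned, and the ribosomal protein list without RNase P genes.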

Results

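The series compared fission yeast cells that overexpress the corepressor subunit Ssn6 with cells carrying the empty plasmid, to find the genes whose transcripts change when Ssn6 is in excess. A total of 2 arrays were hybridised, each with both cultures. The ratio of a gene is that of channel B over channel A after loess, given as the mean over the arrays ± SD (n = 2). The labels give each culture's dye but not which file channel holds it, so directions are given by channel.

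The ssn6 transcript was brighter in channel B on both arrays. Its log2 ratio was 2.05 ± 0.19 (adjusted p = 4.9e-05), with 1.91 on array 1 and 2.18 on array 2. Before normalization the single ssn6 spots were 6.16-fold and 8.1-fold brighter in channel B on array 1, and 8.86-fold and 8.29-fold on array 2. The tup12 gene had no matched probe. The ratio of tup11, which encodes a partner subunit of the corepressor, was 0.26 ± 0.14 and did not pass (adjusted p = 0.265). The labelled dye swap would place the Ssn6 culture in opposite dyes on the arrays, and ssn6 had the same sign on both.

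Of 4841 genes tested, 1389 passed the adjusted p, 572 of them higher and 817 lower in channel B than in channel A. At least 1.5-fold in the same direction on both arrays were 867 genes, 304 higher and 563 lower, against 30 genes changed that much in opposite directions. The 867 genes all lay among the 1389. The arrays' ratios correlated across genes with Pearson r = 0.808 and Spearman rho = 0.702, and 75.9% of genes had the same sign. Genes are not independent replicates, and these are descriptions across genes. With median centring in place of loess, 47.7% of 1594 genes past the adjusted p were higher in channel B, against 41.2% here. Of the genes changed 1.5-fold on both arrays, 46.7% were then higher, against 35.1%. With the authors' deposited values, which rest on 1 spot per array for most genes, 48.5% of 974 such genes were higher. There, 0 genes passed in limma, and 1782 had an unadjusted p under 0.05 against 2022 here.

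**Figure D1:**
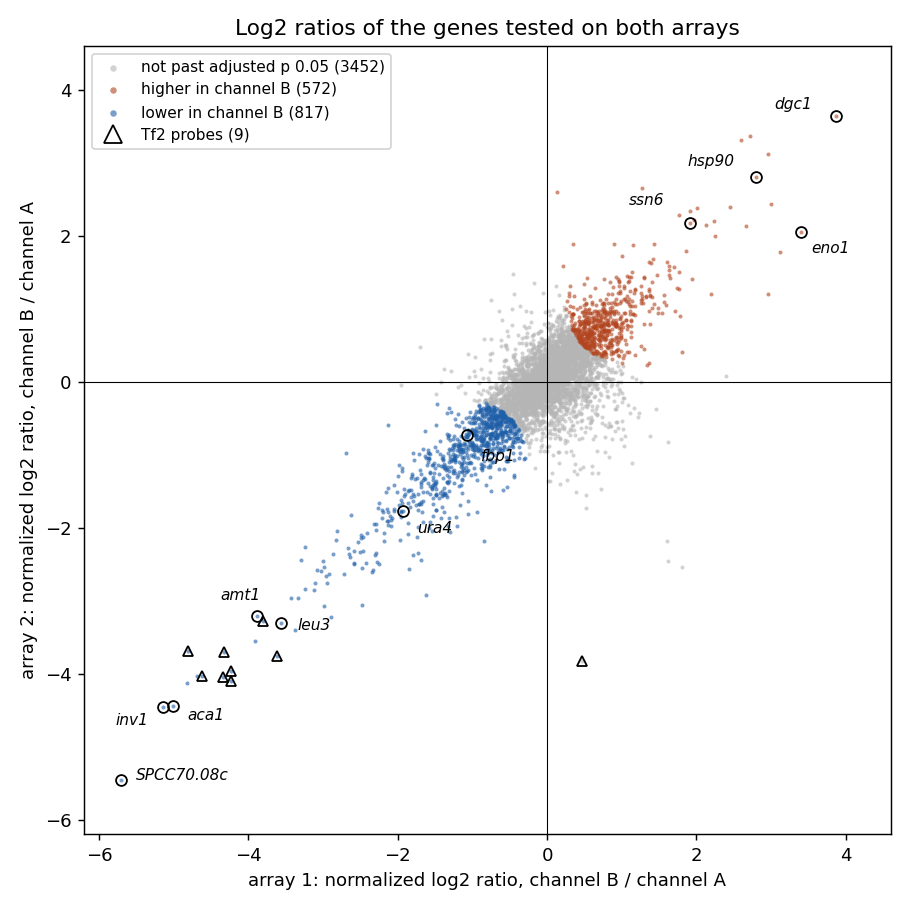
Normalized log2 ratio of channel B over channel A on array 1 (horizontal axis) and array 2 (vertical axis) for the 4841 genes tested, one point per gene. The 572 genes higher and 817 lower past adjusted p 0.05 lie along the diagonal, since the test favours genes whose arrays agree. Of the 9 Tf2 probes 1, Tf2-3, lies off it at 0.46 on array 1 and -3.83 on array 2.

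The 12 highest and 12 lowest genes were ranked by the smaller of the arrays' absolute ratios. Those highest in channel B included the chaperone genes hsp90 and ssa1. The highest ratio was that of dgc1, at 3.75 ± 0.17 (adjusted p = 2.07e-06). It was followed by xan1, a xanthine dioxygenase gene (3.05 ± 0.46), and by hsp70 (3.04 ± 0.11), a probe that keeps the file's name. SPAC11D3.15 had a ratio of 2.96 ± 0.51, hsp90 2.80 ± 0.01, and ssa1, an Hsp70 family gene, 2.72 ± 0.40. The cyclophilin gene wis2 (2.42 ± 0.04), the proline permease gene put4 (2.22 ± 0.03), the glycine cleavage gene gcv3 (2.19 ± 0.27) and SPAC977.14c (2.14 ± 0.01) followed. The enolase probe eno1 (2.73 ± 0.95) and the S-adenosylmethionine synthetase gene sam1 (2.40 ± 0.38) completed the 12. All 4 spots of eno1 and all 4 of sam1 held saturated pixels (1 of hsp90 did), so the ratios of eno1 and sam1 have no value without saturated spots. The adjusted p of the 12 genes ranged up to 0.000167, that of eno1.

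The genes lowest in channel B by that ranking were led by SPCC70.08c, at -5.58 ± 0.18 (adjusted p = 6.58e-07). The invertase gene inv1, which is repressed by glucose, followed at -4.80 ± 0.49, which is 27.9-fold higher in channel A. Next were aca1 (-4.73 ± 0.40), SPCC794.05c (-4.47 ± 0.50) and SPBC1E8.04c (-4.36 ± 0.47). The other 7 were probes of the Tf2 retrotransposons, from -3.69 ± 0.10 for Tf2-12 to -4.33 ± 0.42 for Tf2-6. Saturated pixels occurred in all spots of SPBC1E8.04c, in 1 spot each of SPCC70.08c and SPCC794.05c, and in at least 3 spots of each of these Tf2 probes. The plasmid marker gene ura4, of pyrimidine synthesis, was lower in channel B at -1.86 ± 0.11 (adjusted p = 7.59e-05). Both cultures grew under selection for a plasmid, and the cause of this difference was not tested. The fructose-1,6-bisphosphatase gene fbp1 was lower at -0.91 ± 0.24 (adjusted p = 0.00461).

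**Figure D2:**
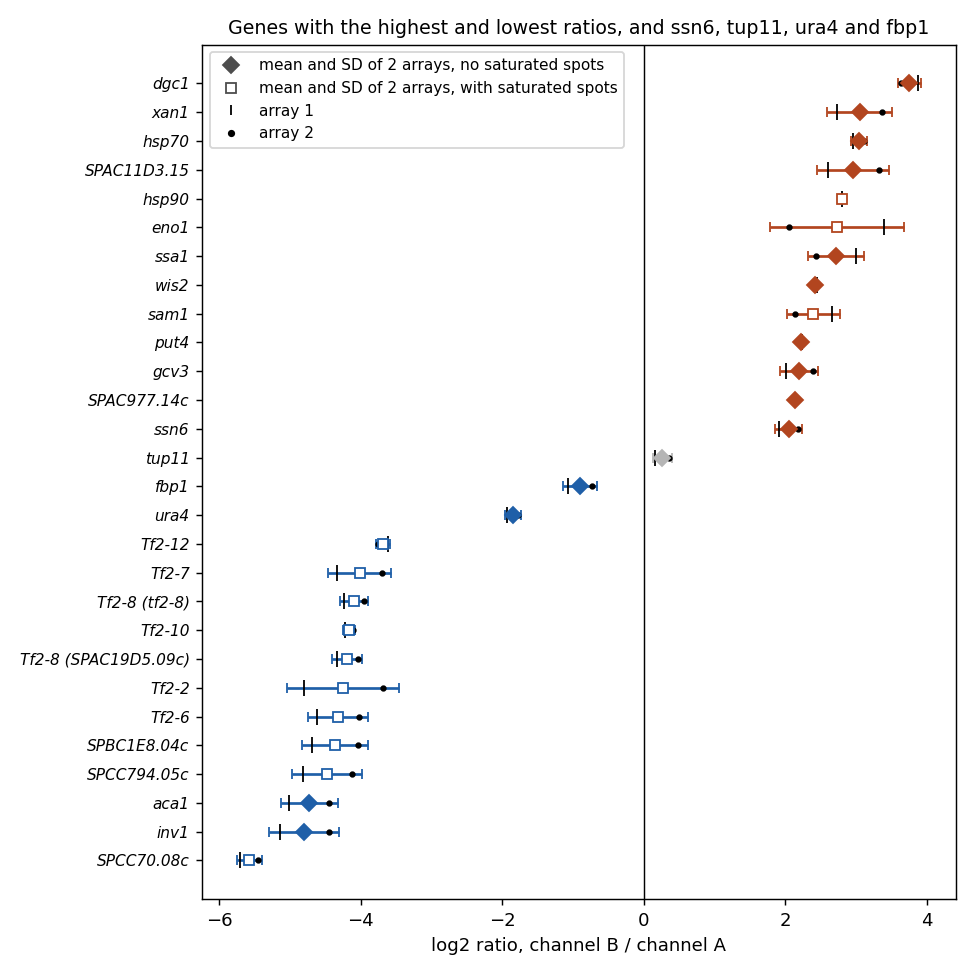
Log2 ratio of channel B over channel A for the 12 highest and 12 lowest genes and for ssn6, tup11, ura4 and fbp1, as the mean and SD of 2 arrays with the value of each array marked. Open squares are genes with saturated pixels in at least 1 spot; dgc1 is highest at 3.75 and SPCC70.08c lowest at -5.58.

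Of the 26 gene lists tested, 12 passed camera, 5 toward channel B and 7 toward channel A. The preset correlation of 0.01 treats members as nearly independent, so these p-values may be too small where probes share hybridisation signal. With an estimated correlation 0 lists passed, the smallest unadjusted p was 0.0979, and each of the 12 lists had an adjusted p of 0.565. That estimate and the test that uses it rest on 1 residual degree of freedom, which leaves little room for a list to pass. The wtf list did not pass there although its estimated correlation was -0.039. The loss of the calls therefore does not show that members of a list vary together, and it leaves the calls open.

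Amino acid biosynthesis genes were mostly lower in channel B. Of 37 members, 27 were lower, 2 higher and 8 did not pass, with a median of -1.08 (adjusted p = 3.17e-09; 0.565 with an estimated correlation). Adjusted over the list alone, 27 were lower and 4 higher. The lowest members were leu3 of leucine synthesis (-3.44 ± 0.18), asn1 of asparagine synthesis (-3.15 ± 0.26), lys3 of lysine synthesis (-2.98 ± 0.19) and arg5 of arginine synthesis (-2.81 ± 0.21). Saturated pixels occurred in 1 spot of leu3 and 2 of asn1, and with median centring the list median was -0.70 and arg5 had -1.87. The members higher in channel B were the glutamine synthetase gene gln1 (1.16) and met14 (0.69).

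Retrotransposon and repeat family probes were mostly lower in channel B. Of 9 Tf2 probes 8 were lower, with a median of -4.10 (adjusted p = 6.67e-11), and adjusted over the list alone 9 were lower. All 9 held saturated spots. The exception, Tf2-3, had 0.46 on array 1 and -3.83 on array 2, and counts among the 9 only through the mean of the arrays. Of 22 wtf family probes, 14 were lower and 8 did not pass, with a median of -1.12 (adjusted p = 3.12e-08; 15 lower adjusted over the list alone). Examples were wtf9-pseudo (-1.56 ± 0.02), wtf4-pseudo (-1.50 ± 0.10), wtf10 (-1.46 ± 0.08) and wtf3-pseudo (-1.42 ± 0.05). The members of each family are related in sequence, and whether their probes share hybridisation signal was not tested. The values of single members are therefore uncertain. Shared signal would also make the adjusted p of both lists at the preset correlation too small. The adjusted p with an estimated correlation was 0.565 for both.

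Core histone genes were lower in channel B. Of 9 probes 8 were lower, and only the H2A.Z variant gene pht1 (0.30) did not pass, with a median of -1.49 (adjusted p = 2.16e-05; 0.565 with an estimated correlation). Adjusted over the list alone, 8 were lower. The list median lay at percentile 4.36 of 10000 random lists matched on intensity, inside their central 95% (-1.66 to 0.37). Intensity bias is therefore not excluded. The other 11 lists that passed lay outside theirs. The matching used the measured signal, which may be wrong for saturated spots. It cannot decide on intensity bias for the Tf2 and glycolysis lists, where 9 of 9 and 8 of 14 members held such spots. The ratios of hht3 (-1.74 ± 0.25), hhf3 (-1.73 ± 0.44), hta2 (-1.49 ± 0.07) and hht2 (-1.49 ± 0.24) came from genes whose copies are close in sequence, and 5 of the 9 probes had saturated spots. Among them were 4 spots of hht2, 2 of hht3 and 1 of hhf3. The ratios of hht2 and hht3 have no value without saturated spots. With print-tip loess hht3 had a ratio of -1.03, and hhf3 had -0.47 and did not pass (adjusted p = 0.0554). With median centring the list median was -0.50 (adjusted p = 0.0471), and hht3 (-0.50), hhf3 (-0.62), hta2 (-0.52) and hht2 (-0.67) were smaller too.

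Core stress genes were mostly lower and chaperone genes mostly higher in channel B. Of 24 core environmental stress genes, 16 were lower, 5 higher and 3 did not pass, with a median of -0.84 (adjusted p = 0.00107; 0.565 with an estimated correlation; 16 lower and 5 higher adjusted over the list alone). The small heat-shock gene hsp9 (-2.93 ± 0.24), the protease gene isp6 (-2.49 ± 0.47), rds1 (-2.46 ± 0.18) and the transcription factor gene pcr1 (-1.94 ± 0.27) were lowest, hsp9 with 3 saturated spots. Of 14 chaperone genes, 8 were higher and 3 lower, with a median of 0.79 (adjusted p = 0.00311; 0.565 with an estimated correlation; 9 higher and 3 lower adjusted over the list alone). They included hsp90, ssa1 and the DnaJ family gene mas5 (1.82 ± 0.04). The lists share hsp9 and hsp16, both lower, and hsp104 and psi1, both higher.

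The ribosomal protein and ribosome biogenesis lists ran higher in channel B. Of 141 members of the ribosomal protein list, 57 were higher, 2 lower and 82 did not pass, with a median of 0.46 (adjusted p = 1.02e-11; 0.565 with an estimated correlation). Adjusted over the list alone, 71 were higher and 2 lower. Examples were rpp203 (1.59 ± 0.07), rps001 (1.37 ± 0.27), rps101 (1.32 ± 0.39) and rps1701 (1.25 ± 0.26), some of which have close paralogs. The list was matched by name prefix and also holds the RNase P subunit genes rpp1 (0.06), rpp21 (0.38) and rpp40 (0.05), none of which passed. Without these 3, an alternative chosen after seeing the data, 57 of 138 were higher and 2 lower, with a median of 0.47 (adjusted p = 7.18e-12). Saturated spots occurred in 66 of the 141, and 35 of the other 75 were higher. The median was 1.21 with median centring and 0.80 with the authors' deposited values. Of 29 ribosome biogenesis genes, 7 were higher and 22 did not pass, with a median of 0.34 (adjusted p = 0.00157; 0.565 with an estimated correlation; 7 higher adjusted over the list alone). These included gar1 (0.95 ± 0.16), rrs1 (0.88 ± 0.18), nop52 (0.84 ± 0.11) and gar2 (0.69 ± 0.08).

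Of 14 glycolysis and fermentation genes, 9 were higher and 1 lower in channel B, with a median of 0.88 (adjusted p = 0.000127; 0.565 with an estimated correlation; 9 higher and 1 lower adjusted over the list alone). Higher members included the glyceraldehyde-3-phosphate dehydrogenase gene gpd3 (2.45 ± 0.96), pdc101 (2.13 ± 0.31) and gpm1 (1.47 ± 0.003), the 3 higher members named by the rule. Another, pgk1, had 2.08 ± 1.24 with saturated spots, and the pyruvate decarboxylase gene pdc201 was lower (-2.32 ± 0.25). All spots of 8 of the 14, gpd3, pdc101 and gpm1 among them, held saturated pixels. Over the 6 members measured without saturated spots the median was 0.33 (adjusted p = 0.335), and with flag C spots only it was 0.30 (adjusted p = 0.112).

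The glucose-repressed and iron-using lists ran lower in channel B, though not all members passed. Of 16 glucose-repressed genes, 7 were lower, 1 was higher (the hexose transporter gene ght2, 0.52) and 8 did not pass, with a median of -0.51 (adjusted p = 0.00209; 0.565 with an estimated correlation; 9 lower and 1 higher adjusted over the list alone). Besides inv1 and fbp1, these were led by gld1 (-2.46 ± 0.05), the mating regulator gene ste11 (-1.24 ± 0.02) and mae1 (-1.03 ± 0.04). With median centring mae1 had a ratio of -0.06 and did not pass (adjusted p = 0.835). Of 11 iron-using genes, 7 were lower and 4 did not pass, with a median of -0.77 (adjusted p = 0.00129; 0.565 with an estimated correlation; 9 lower adjusted over the list alone). The aconitase gene aco1 (-2.13 ± 0.27), isa1 (-1.65 ± 0.49), the glutamate synthase gene glt1 (-1.27 ± 0.17) and bio2 (-0.86 ± 0.14) were lowest. With median centring aco1 had -1.21 and the iron-using list an adjusted camera p of 0.0471 (0.489 with an estimated correlation). With the authors' deposited values the list had 0.0379 (0.472 with an estimated correlation).

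Of 14 G1/S genes under MBF, 5 were higher, 1 lower and 8 did not pass, with a median of 0.43 (adjusted p = 0.0169; 0.565 with an estimated correlation; 8 higher and 1 lower adjusted over the list alone). Higher were rep2 (1.20 ± 0.10), the ribonucleotide reductase gene cdc22 (0.83 ± 0.02) and mik1 (0.70 ± 0.40), and the replication licensing gene cdt1 was lower (-1.08 ± 0.14). With median centring the list had an adjusted camera p of 0.0402 (0.489 with an estimated correlation).

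Several lists held members that went both ways. Over all 4841 genes tested 572 were higher and 817 lower, so a few members each way do not by themselves mark a list. The iron uptake list of 13 genes also holds the biotin transporter gene vht1 and the regulator genes fep1 and php4. Of the 13, 4 were higher, the siderophore transporter genes str1 (1.51 ± 0.33) and str3, frp1 (0.82) and php4 (0.50), and 3 were lower, vht1 (-3.38 ± 0.01), the siderophore synthesis gene sib1 (-1.46 ± 0.34) and fep1 (-0.93). The list had a median of 0.32, a mean of -0.03 and an adjusted p of 0.474, and its counts were the same adjusted over the list alone. The str3 probe was not well above background in channel A, and its level in channel B was at least 2.35-fold higher. Of 13 Pap1 targets 4 were higher and 5 lower (adjusted p = 0.658), with gst2 2.83-fold higher, ctt1 at -1.29 ± 0.53, pap1 at -1.22 ± 0.26 and gst3 at -0.96 ± 0.05. Of 19 mating and nitrogen starvation genes 2 were higher and 6 lower (adjusted p = 0.191), among them the ammonium transporter genes amt3 (-1.86 ± 0.18) and amt1. The amt1 probe was not well above background in channel B, and its level in channel A was at least 10.4-fold higher as a mean over the arrays. Its log2 ratio on array 2 alone was smaller than that, at -3.21, against -3.89 on array 1. Of 26 meiosis genes 2 were higher and 5 lower (adjusted p = 0.191), with dmc1 at -1.41 ± 0.13, isp3 at -1.30 ± 0.18, spo3 at -0.82 ± 0.04 and mde6 at -0.74 ± 0.24. Of 26 respiration genes 7 were higher and 2 lower (adjusted p = 0.181), with cox9 at 0.92 ± 0.23, cox8 at 0.88 ± 0.06, qcr10 at 0.81 ± 0.23 and cox12 at 0.78 ± 0.02. Of 21 sterol and hypoxia genes 6 were higher and 1 lower (adjusted p = 0.191), with erg28 at 0.90 ± 0.31, erg10 at 0.82 ± 0.20, erg1 at 0.75 ± 0.01 and ins1 at -0.93 ± 0.05; with median centring erg10 had 1.34. The respiration and sterol lists passed toward channel B with median centring (adjusted p = 0.00528 and 0.00796; 0.489 for both with an estimated correlation). They also passed with the authors' deposited values (adjusted p = 0.0489 and 0.0471; 0.472 for both with an estimated correlation).

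The other lists did not pass. For copper uptake 3 of 4 genes were lower (adjusted p = 0.0892), and for cell separation 4 were higher and 2 lower of 17 (adjusted p = 0.0723). Cell separation passed toward channel B with print-tip loess (adjusted p = 0.0325) and without saturated spots (adjusted p = 0.0268), and copper uptake toward channel A with the authors' deposited values (adjusted p = 0.0471). With an estimated correlation these were 0.512, 0.674 and 0.472. Of 13 flocculation genes 2 were higher and 1 lower (adjusted p = 0.481), and of 20 silencing and chromatin genes 1 was higher and 2 lower (adjusted p = 0.658). Phosphate genes had 1 higher and 2 lower of 6 (adjusted p = 0.411), zinc genes 1 and 2 of 5 (adjusted p = 0.155) and thiamine genes 1 and 2 of 5 (adjusted p = 0.792). Of 6 pyrimidine genes 2 were higher and 1, ura4, was lower (adjusted p = 0.547). The corepressor and telomeric helicase lists had 2 and 1 members and were not tested, and the only helicase probe had a ratio of -0.05.

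**Figure D3:**
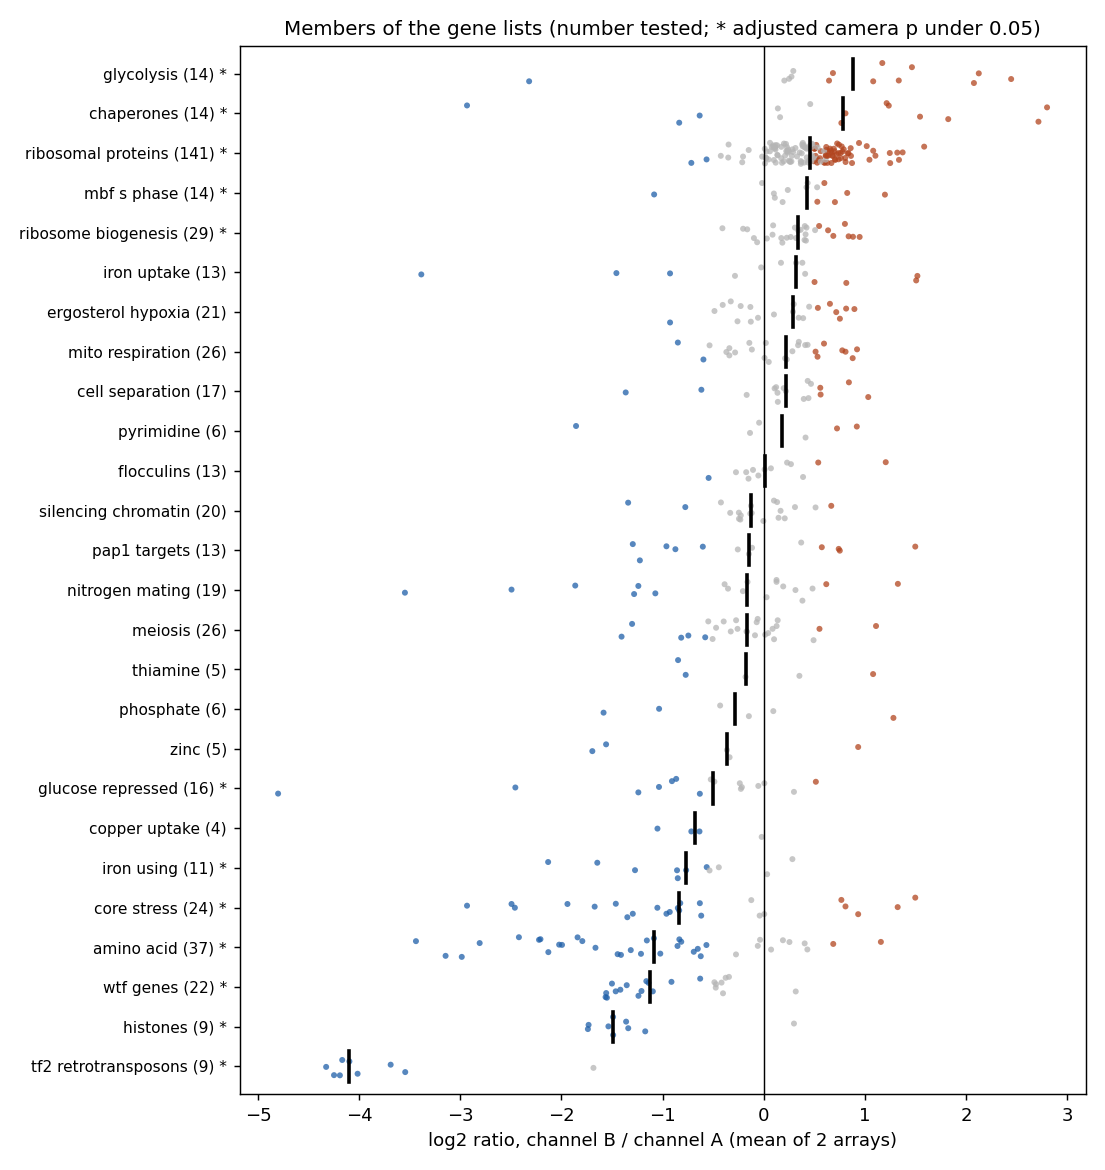
Log2 ratio of channel B over channel A (mean of 2 arrays) of each member of the 26 gene lists tested, coloured where the gene passed adjusted p 0.05 and grey where it did not, with a black bar at each list's median. Medians run from -4.10 for the Tf2 probes to 0.88 for glycolysis, where saturated pixels occurred in the highest members.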

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

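Both probes below lie outside the genes tested and were above the limit set by the negative control spots, with a ratio of at least 1.5-fold in the same direction on both arrays. They are 2 of 53 reporter, intergenic, intronic or missing probes, of which 15 were above that limit. The probe Sc_ACT1A_80 had a log2 ratio of channel B over channel A of 0.67, with 0.64 on array 1 and 0.70 on array 2. The probe tap_tag had a log2 ratio of -1.16, with -1.29 on array 1 and -1.03 on array 2. No explanation was tested for either.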

How the results depend on the processing

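The sign of array 1 turned, the removal of saturated spots, flag C spots and normexp were chosen after seeing the data, as was the ribosomal protein list without RNase P genes (median 0.47), the other alternatives before the data were examined. The ratio of ssn6 stayed above 0 under every alternative and passed except where named here; with flag C spots only it has no value, since both its spots on array 1 have another flag in one channel. Each array holds both cultures, so the test of the ratios is itself paired.

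The authors' deposited values gave 0 genes past the adjusted p, 0 higher and 0 lower, and ssn6 at 2.29 (adjusted p = 0.0741). There, 185 genes had the same rounded value on both arrays and the prior had 1.32 degrees of freedom. The folds stayed about as large: 974 genes changed 1.5-fold on both arrays, 472 higher and 502 lower, with dgc1 at 3.92 and inv1 at -4.60. Median centring gave 462 higher genes. The cause of the higher share was not tested. At 2-fold, 370 genes changed the same way on both arrays, 85 higher and 285 lower. The arrays' correlation was 0.795 without the filter on dim probes and 0.795 without saturated spots.

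With the sign of array 1 turned, the correlation was -0.808 by construction. No gene passed (0, with 0 higher and 0 lower, and 6 at an unadjusted p under 0.05), 30 genes changed 1.5-fold on both arrays (3 higher, 27 lower), ssn6 had 0.13, 0 of 90 named genes passed, and 1 list, meiosis, passed in place of the 12. The adjusted camera p of the meiosis list was then 8.6e-06, and 0.972 with an estimated correlation.

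With one array alone, 1380 to 1419 genes changed 1.5-fold, 576 to 595 of them higher, since the other array no longer has to agree. The ratio of ssn6 was then 1.91 to 2.18. The adjusted p has no value with 1 array.

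With an estimated correlation 0 lists passed. The counts that follow leave out the turned sign and the estimated correlation. Of named genes, 861 values kept their direction and side of the threshold and 90 no longer passed, 88 of them with the authors' values. Of list values 250 kept it, 7 newly passed (respiration, sterol, cell separation and copper uptake) and 2, both of glycolysis, no longer passed. The Tf2 list has no value without saturated spots.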

Other observations

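Some gene groups were put together after the values were seen, around members such as sam1, xan1, hsp70 and wis2 that were already among the 12 highest. They describe values, and no test of them was made. Of 12 genes of sulfate uptake and assimilation, 7 were higher in channel B and 0 lower. They included the sulfate transporter gene sul2 (2.12 ± 0.17), the ATP sulfurylase gene sua1 (1.61 ± 0.03) and sam1, whose spots were saturated. Of 8 genes of purine breakdown and urease, 5 were higher, xan1, dal2 (1.67 ± 0.38) and the uricase gene uro1 (1.63 ± 0.18) among them. Of 14 chaperonin, co-chaperone and other chaperone genes outside the chaperone list, 8 were higher and 0 lower. Among the higher were hsp70, wis2, pss1 (1.66 ± 0.32), aha1 (1.35 ± 0.09) and cct8 (0.95 ± 0.005). The chaperonin genes cct2, cct3, cct5, cct6 and cct7 did not pass. Of 4 glycine cleavage genes 2 were higher and 1 lower.

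All 5 ftm family members tested passed as lower in channel B. The ratios of ftm1 (-2.83 ± 0.35), ftm4 (-2.73 ± 0.38) and ftm3 (-1.69 ± 0.03) were measured. The probes of ftm2 and ftm7 were not well above background in channel B, and their levels in channel A were at least 5.86-fold and 2.93-fold higher. Whether these probes share hybridisation signal was not tested. All 3 ammonium transporter genes were lower, amt1 with only a bound. Both snz1 and sno1 were lower, at -1.98 ± 0.15 and -2.50 ± 0.20, snz1 with saturated spots.

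Chromosome ends were also looked at after the values were seen, with the outermost 50 protein-coding genes at each end of chromosomes I and II. On chromosome I, 28.2% of 39 genes tested at the left end and 30% of 40 at the right were lower in channel B, and 23.1% and 25% were higher. On chromosome II, 50% of 22 and 37.5% of 40 were lower, and 4.55% and 2.5% were higher. Among other genes 16% of 4442 were lower and 12% higher. No test of the ends was made.

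Of the tests that follow, those of the channels and of saturated spots were chosen after the result was seen. Both arrays ran the same way. The labels give each culture's dye but do not match dyes to the file channels. If channel A were Cy3 and channel B Cy5 on both arrays, the dye swap in the labels would put ssn6 below 0 on array 1, and it was 1.91 there, which argues against that reading. The columns may instead hold one culture each. Channel B would then likely be the Ssn6 culture, a reading that rests on the ssn6 ratio itself and on no label. Of 6 kinds of control spots, 4 had the same sign relative to genes on both arrays and 2 opposite signs, so a real dye swap and the same dye on the same culture cannot be told apart.

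The ribosomal protein and glycolysis lists ran higher in channel B, where brighter spots also had higher raw ratios. The median of the ribosomal protein list lay at percentile 100 of 10000 random lists matched on intensity, which argues against intensity bias left after loess. The matching used the measured signal, which may be wrong for the 66 members with saturated spots. The other 75 had a median of 0.48. The random lists took the loess values as given, so the loess curve itself was not tested. The 98 of its 141 members measured without saturated spots had an adjusted p of 3.35e-12 (0.674 with an estimated correlation), which at the preset correlation argues against saturation for these 98. The other 43 have no value without saturated spots, so saturation stays open for them. For glycolysis, only 6 of 14 members were left without saturated spots (adjusted p = 0.335), so saturation and a change of these transcripts cannot be told apart. A difference between the cultures stays open for both.

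The ratios of genes next to each other on a chromosome were weakly correlated. Neighbours measured in different parts of the spot order correlated across pairs with r = 0.0856 on array 1 and 0.108 on array 2. The 95th percentiles in 1000 shuffled gene orders were 0.0227 and 0.021. The array grid is not given, so such neighbours may lie at matching positions of a repeated layout. Uneven signal that recurs at those positions would also correlate them. The test therefore cannot decide on uneven signal across the slide, which stays open. Without the outermost 50 genes of each end of chromosomes I and II the correlations were 0.0647 and 0.091. They were smaller but stayed above the 95th percentiles of shuffled orders (0.0228 and 0.0213). This argues against shared hybridisation of repeat families at those ends as the only source. Genes elsewhere, repeat families included, were kept, so shared hybridisation there stays open. Carry-over between wells of the printing plates was not tested, and shared regulation of neighbours is one hypothesis that may apply.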
